A study of Mus musculus with 8 samples.

How the data were processed

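Total RNA was extracted with Trizol and RNeasy columns and labelled with biotin, per the labels' protocols, from wild-type and Med23-/- mouse embryonic fibroblasts. Each of the 8 samples was run on 1 array, with 2 arrays in each of 4 groups. The platform is not named in the labels used here, and the probe set names are of the Affymetrix mouse type. The deposited values are intensity per probe set, made with MAS5 per the submitters' processing notes, which give no version. They are positive, on a linear scale and reach 95220, and the authors' scaling left each array with the same mean after trimming 2% at each end (2500.6 to 2500.8). MAS5 subtracts mismatch signal, so low values are noisy and ratios to them are uncertain. Detection calls were not given in the sources used here. The ratio of 3' to 5' signal lay between 1.029 and 1.065 for Actb and between 0.774 and 0.840 for Gapdh on the 8 arrays. For Tfrc it lay between 1.886 and 4.23, highest on starved wild-type array 1 and lowest on starved knockout array 2.

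The deposited table held 22690 probe sets. The 64 control probe sets were left out, and of the other 22626 those at or above the array's own 40th percentile on at least 2 of the 8 arrays were tested, which were 14947 (66.1%). Probe sets were paired with genes through the table given for the arrays, in which 20380 named a single gene, 691 several and 1555 none; the tested ones covered 8453 genes. A gene in a list was represented by its probe set with the highest mean log2 signal. Values were analysed as log2 of signal plus 16. The fit was limma 3.58.1 in R 4.3.3, with group means over all 8 arrays, eBayes with a mean-variance trend, two-sided tests and Benjamini-Hochberg adjustment over the tested probe sets, and a call was an adjusted p under 0.05. It had 4 residual and 6.07 prior degrees of freedom. The 5 comparisons were serum in each genotype, the interaction of genotype and serum, and knockout against wild type in starved and in stimulated cells. All 8 arrays were used. With 2 arrays against 2, an exact two-sided permutation test of a single gene cannot give a p under 0.333, so calls rest on the spread pooled across groups and probe sets.

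The labels name a fold change over 2 as the study's rule, so probe sets whose group means differed by over 1 on the log2 scale with no overlap of arrays were also counted. As background, the same count was made between the second and the first arrays; each side then held an array of both groups, so real differences lower that count. For the interaction all combinations of arrays had to be apart, which has another chance level, taken from simulated normal values. Sets of genes were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry, over 28 lists of 555 members, 495 of them named on the array, with Benjamini-Hochberg adjustment over the lists of a comparison. The tests, the lists, the filter and the alternatives, apart from a pseudocount of 256 and, for lists other than the immediate early factors, median centring and leaving out arrays, which were chosen after seeing the data, as was the simulated chance level for the interaction, were fixed before the data were examined. Genes were named by a rule: Med23, Egr1 and the immediate early transcription factors; in each comparison up to 10 called genes up and 10 down with the largest change and no overlap of groups; and up to 4 members of each list with the smallest p.

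The procedure was tested on simulated data of 14947 probe sets with 200 changed in each of 5 runs. For the wild-type serum comparison, 77.6% of changes of 1 and 97.6% of changes of 2 on the log2 scale were recovered, and 6.62% of calls were false. For the interaction the shares were 44.8% and 90%, with 6.52% of calls false. The alternatives were a pseudocount of 1, 64 or 256, quantile normalization or centring of each array on its median, and no filter or a 60th percentile filter. Others were no mean-variance trend, a fit to the arrays compared only, the set number as a block and 1 probe set per gene. The last were leaving out probe sets with any letter suffix in their name, such as a, s or x, and leaving out each array in turn. Set numbers 1 and 2 occur in every group, but the labels do not say that they pair the samples. The figures were drawn with matplotlib.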

Results

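Expression was measured on 8 mouse arrays from embryonic fibroblasts, connective tissue cells taken from embryos and here passaged through crisis, the stage at which most cells of a primary culture stop dividing before an immortal line grows out. Wild-type (WT) cells and Med23-/- knockout (KO) cells were each starved for 16 h in 0.5% serum. For each genotype 2 arrays came from cells kept starved and 2 from cells given 20% serum for 30 min, so every group mean below has n = 2 arrays. The stated purpose was to find genes whose response to serum is affected by the loss of MED23, with immediate early genes such as Egr1 looked at in detail. Immediate early genes are those that serum growth factors switch on within minutes without new protein synthesis. The labels do not say whether the replicates were separate cultures, so the p-values below measure only the spread between these samples. Each array had a trimmed mean signal between 2500.6 and 2500.8 and a median signal between 765.6 and 924.4. Replicate arrays correlated across probe sets at r between 0.976 and 0.984, arrays of the same genotype in the other serum state at 0.930 to 0.962, and arrays of the other genotype at 0.750 to 0.805. The first principal component held 74.0% of the variance and parted the genotypes, and the second held 14.6% and parted starved from stimulated cells.

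Med23 itself, which encodes a subunit of Mediator, the complex that links DNA-bound activators to RNA polymerase, was close to absent in knockout cells. Its probe set read 4901 and 5410 in starved wild-type cells against 28 and 132.5 in starved knockout cells, and 3595 and 3577 against 34.61 and 36.91 after serum. The log2 difference was -6.00 ± 0.449 (SE) in starved cells, with limma adjusted p = 3.81e-06, and -6.12 ± 0.449 after serum, with adjusted p = 3.52e-06. The knockout signals lay near the floor of the arrays, so these sizes depend on the added constant, and the starved value was -5.12 and -6.88 without starved knockout array 1 or 2. Whether the probe set lies in the deleted part of the gene is not given in the sources used here. Egr1, a zinc finger transcription factor and a standard readout of growth factor signalling, rose with serum in both genotypes. Its signal went from 6993 and 7545 to 44250 and 44090 in wild-type cells, a log2 change of 2.60 ± 0.156 (adjusted p = 5.63e-06). In knockout cells it went from 1336 and 1965 to 40510 and 39300, a log2 change of 4.61 ± 0.156 (adjusted p = 5.6e-08). The response was thus larger in knockout cells by 2.01 ± 0.221 (adjusted p = 0.00201). Starved knockout cells held less Egr1 than starved wild-type cells, by -2.15 on the log2 scale (adjusted p = 3.1e-06), while the difference after serum was -0.15 (adjusted p = 0.461).

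**Figure D1:**
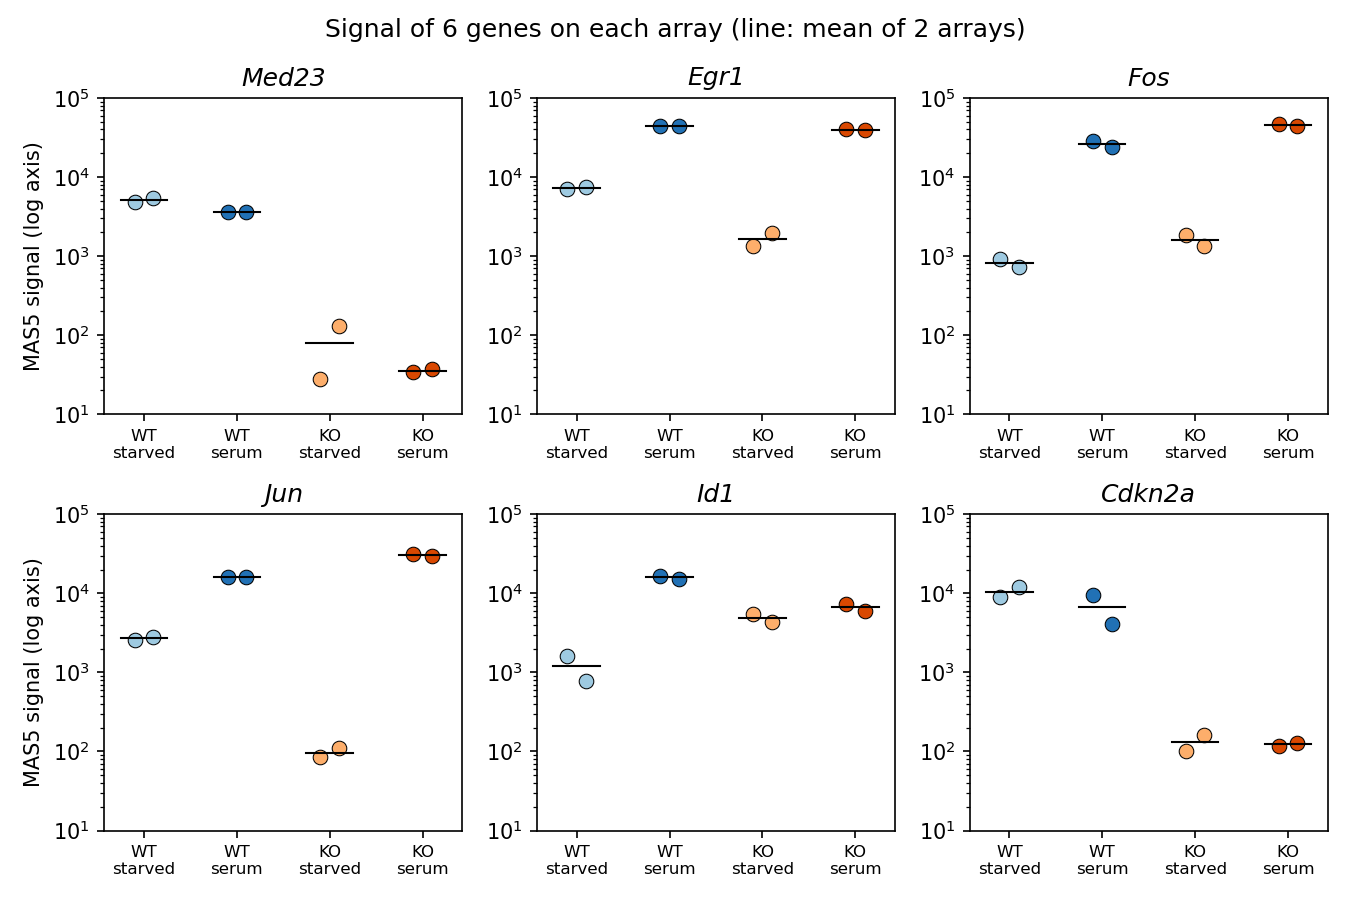
MAS5 signal (log axis) of 6 genes on each of the 8 arrays, by genotype and serum state; points are arrays and lines are means of 2 arrays. Egr1 averaged 7269 in starved wild-type and 1651 in starved knockout cells, and 44170 and 39910 after serum, while Med23 averaged 5156 and 80.26 in starved cells.

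Serum in wild-type cells answered which genes a 30 min stimulus changes when MED23 is present. The strongest rises were of immediate early genes. Fosb, a partner in the AP-1 transcription factor, rose 70.1-fold (log2 6.13 ± 0.157, adjusted p = 2.39e-08), from a mean signal of 268.7 to 19880. Arc rose 56.8-fold (log2 5.83 ± 0.3), Nr4a1, an orphan nuclear receptor, 36.4-fold (log2 5.19 ± 0.171) and Fos 31.2-fold (log2 4.97 ± 0.168). Ppp1r3c, a glycogen-targeting subunit of protein phosphatase, fell 23.1-fold (log2 -4.53 ± 0.277, adjusted p = 6e-06), while a second Ppp1r3c probe set at -1.80 did not pass (adjusted p = 0.0569). Arc averaged 38.93 in starved cells and Ppp1r3c 70.87 after serum, near the floor of the arrays, so their folds depend on the added constant.

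Of 27 measured immediate early transcription factors, 22 rose, none fell and 5 did not pass the test in wild-type cells, with a median log2 change of 2.54. Adjusted over the list alone, 24 rose and 1 fell. Egr2 rose 38.8-fold, Junb 7.14-fold, Jun 5.93-fold and Srf, the factor that binds serum response elements, 3-fold. The list as a group was shifted up (camera adjusted p = 6.83e-36, and adjusted p = 0.0141 with an estimated correlation). Early feedback genes, which encode phosphatases, RNA-decay factors and other brakes on signalling, gave 17 rises, 1 fall and 9 not past the test out of 27 (21 and 4 adjusted over the list alone), with a median of 0.94. Zfp36, which destabilises AU-rich mRNAs, rose 8.71-fold, Btg2 12.5-fold and Errfi1, an inhibitor of the EGF receptor, 17.6-fold. That list had camera adjusted p = 5.2e-19, and adjusted p = 0.0138 with an estimated correlation, and its 1 fall was lost (0 fell) without any array other than starved wild-type array 1. Early secreted proteins gave 10 rises and no falls among 18 (12 and 0 adjusted over the list alone), with a median of 1.18 and camera adjusted p = 2.81e-13 (adjusted p = 0.0141 with an estimated correlation). Among them the cytokine Lif rose 26.9-fold, the chemokine Cxcl1 13.2-fold and the EGF-family ligand Hbegf 10.8-fold.

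Targets of TGF-beta and BMP signalling rose in wild-type cells in 8 of 15 cases, with 1 fall and 6 not past the test (9 and 1 adjusted over the list alone), a median of 0.62 and camera adjusted p = 3.95e-09 (adjusted p = 0.0307 with an estimated correlation). The Id genes, which encode inhibitors of basic helix-loop-helix factors, led this group. Id1 rose 14.1-fold (log2 3.81 ± 0.273), Id2 13.7-fold (log2 3.78 ± 0.233) and Id4 11.2-fold (log2 3.49 ± 0.193), and Smad7, an inhibitor of the pathway, rose 4.91-fold. NF-kB feedback genes gave 7 rises and no falls among 15 (8 and 0 adjusted over the list alone), including Tnfaip3 at 12.4-fold and Nfkbia at 1.58-fold. Their median was 0.66 with camera adjusted p = 1.13e-07, and adjusted p = 0.0606 with an estimated correlation; 3, 3 and 4 rose without starved wild-type array 1, starved wild-type array 2 or stimulated wild-type array 2. Targets of SRF in the actin cytoskeleton gave 6 rises and no falls among 26 (7 and 0 adjusted over the list alone), with Itga5 up 2.83-fold, a median of 0.12 and camera adjusted p = 5.81e-05 (adjusted p = 0.431 with an estimated correlation). The median was 0.05 and 0.20 without starved wild-type array 1 or 2. Unfolded-protein and heat-shock genes gave 2 rises and no falls among 17 (3 and 0 adjusted over the list alone), with Dnajb1 up 3.75-fold, a median of 0.12 and camera adjusted p = 0.0317 (adjusted p = 0.479 with an estimated correlation). That call had adjusted p = 0.382 and a median of -0.01 without starved wild-type array 1, and adjusted p = 0.0688 without stimulated wild-type array 1. The median was 0.22, with 1 rise, without starved wild-type array 2, and 0.18 without stimulated wild-type array 2.

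Among falls in wild-type cells, Zfp503, a zinc finger protein, fell 15.4-fold (log2 -3.95 ± 0.47), Txnip, an inhibitor of thioredoxin and of glucose uptake, 9.13-fold (log2 -3.19 ± 0.291), Zkscan14 7.33-fold and Osr1 5.42-fold. Zfp503 and Zkscan14 averaged 23.37 and 87.03 after serum, near the floor, and a second Zfp503 probe set fell by -1.60 on the log2 scale. In all, 619 of 14947 probe sets passed the limma test with Benjamini-Hochberg adjustment in wild-type cells, 365 up and 254 down. By the rule of over 2-fold with no overlap of arrays, 453 passed, against 127 when the second arrays were set against the first. The groups did not overlap for 50.3% of probe sets, where chance gives 33.3%. The count of 619 fell to 312 and 334 without starved wild-type array 1 or 2, and to 338 and 399 without stimulated wild-type array 1 or 2.

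Serum in knockout cells asked the same question in the Med23-/- line. Jun, the main partner of Fos in AP-1, rose 275-fold (log2 8.10 ± 0.14, adjusted p = 7.27e-10), from a mean signal of 96.55 to 30780. The starved signals of 84.01 and 109.1 lay below the 40th percentile of their arrays, so the fold depends on the added constant. A second Jun probe set, with a mean of 552.8 in starved cells, rose by 4.77 ± 0.165 on the log2 scale (adjusted p = 5.79e-08). The stress-responsive factor Atf3 rose 177-fold (log2 7.47 ± 0.528), Egr2 117-fold (log2 6.87 ± 0.194), Arc 91.3-fold (log2 6.51 ± 0.3) and Fosb 56.8-fold (log2 5.83 ± 0.157). Ccl2, a chemokine that draws monocytes, rose 42.5-fold (log2 5.41 ± 0.3). Ppp1r3c fell 102-fold (log2 -6.67 ± 0.277, adjusted p = 2.01e-07). Atf3, Egr2 and Arc averaged 94.01, 55.31 and 52.62 in starved cells and Ppp1r3c 60.95 after serum, so these folds depend on the added constant too.

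Among immediate early transcription factors in knockout cells, 25 rose, 1 fell and 1 did not pass the test, and adjusted over the list alone 25 rose and 1 fell. The median was 2.93 with camera adjusted p = 7.94e-31, and adjusted p = 0.0262 with an estimated correlation. Nr4a1 rose 39.5-fold, Fos 28.4-fold, Junb 17-fold and Maff 15.6-fold. Feedback genes gave 23 rises, 1 fall and 3 not past the test of 27 (23 and 2 adjusted over the list alone), with a median of 2.60, or 1.71 without starved knockout array 1, and camera adjusted p = 6.19e-21 (adjusted p = 0.0114 with an estimated correlation). Btg2 rose 22.4-fold, Zfp36 20.6-fold and the serum- and glucocorticoid-regulated kinase Sgk1 8.37-fold. Early secreted proteins gave 12 rises, 1 fall and 5 not past the test of 18 (12 and 1 adjusted over the list alone), with a median of 1.72 and camera adjusted p = 1.09e-09 (adjusted p = 0.0262 with an estimated correlation), including Cxcl1 at 28.7-fold, Hbegf at 19-fold and Ptgs2, the inducible cyclooxygenase, at 15.7-fold. The single falls in these lists depended on single arrays. That of the transcription factors was lost (0 fell) without starved knockout array 2 or either stimulated knockout array, and that of the secreted proteins without starved knockout array 1 or stimulated knockout array 2. Of feedback genes 0 fell without either starved knockout array or stimulated knockout array 1, and 2 fell without either starved wild-type array.

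NF-kB feedback genes in knockout cells gave 9 rises and 1 fall among 15 (9 and 2 adjusted over the list alone), with Tnfaip3 up 15-fold, a median of 0.95 and camera adjusted p = 1.37e-06 (adjusted p = 0.098 with an estimated correlation). Unfolded-protein and heat-shock genes gave 9 rises and 2 falls among 17 (9 and 2 adjusted over the list alone), with the chaperone Hspa1a up 3.06-fold and Atf4 2.06-fold, a median of 0.49 and camera adjusted p = 1.34e-05 (adjusted p = 0.26 with an estimated correlation). Cholesterol genes gave 7 rises and 1 fall among 15 (7 and 1 adjusted over the list alone), with Cyp51 up 3.74-fold, Stard4 3.04-fold and Sc5d 2.94-fold. Their median was 0.25 with camera adjusted p = 0.00353 (adjusted p = 0.771 with an estimated correlation). SRF targets gave 7 rises and no falls among 26 (7 and 0 adjusted over the list alone), with a median of 0.11 and camera adjusted p = 0.000704 (adjusted p = 0.515 with an estimated correlation), and p53 targets 7 rises and 2 falls among 20 (7 and 2 adjusted over the list alone), with a median of 0.10 and camera adjusted p = 0.00472 (adjusted p = 0.26 with an estimated correlation). The SRF median was 0.20 after quantile normalization and 0.21 after median centring; the p53 median was 0.23 and 0.21 under these, and 0.18 without starved knockout array 1. TGF-beta and BMP targets gave 5 rises, 2 falls and 8 not past the test of 15 (5 and 3 adjusted over the list alone). Their median was -0.25 while their mean was 0.075, and the list did not pass (camera adjusted p = 0.587). The median was -0.03 and -0.46 without starved knockout array 1 or 2, and -0.14 after median centring. Smad6 fell 2.57-fold and Smad7 rose 2.8-fold, and 4 fell without starved knockout array 2. Without stimulated knockout array 1 or 2, 4 cholesterol genes and 4 SRF targets rose, and the 2 falls among p53 targets were lost (0 fell); 1 fell without any other array. The fall among NF-kB genes was lost (0 fell) without starved knockout array 2 or stimulated knockout array 1, and that among cholesterol genes without stimulated knockout array 2. The 2 falls among unfolded-protein and heat-shock genes were lost (0 fell) without starved knockout array 2, either stimulated wild-type array or either stimulated knockout array, and after median centring, and 1 fell without either starved wild-type array.

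Several falls in knockout cells exceeded 9-fold. Zkscan14 fell 17.5-fold (log2 -4.13 ± 0.362), Tmpo, a nuclear lamina protein, 12.2-fold (log2 -3.61 ± 0.481), Zfp319 10.4-fold, Fam43a 9.7-fold and Fbxo32, a muscle-atrophy ubiquitin ligase, 9.28-fold (log2 -3.21 ± 0.195). Zkscan14, Tmpo, Zfp319 and Fbxo32 averaged 37.07, 59.08, 48.94 and 62.56 after serum, near the floor. Brighter probe sets of Tmpo gave -0.01, -0.18 and -0.72 on the log2 scale, and a brighter probe set of Zfp319 gave -1.20. In all, 3455 of 14947 probe sets passed in knockout cells, 1395 up and 2060 down, and 1040 passed the rule of over 2-fold, against 92 between the second and first arrays. The groups did not overlap for 62.5% of probe sets, where chance gives 33.3%. The median change of all tested probe sets was -0.13, and the balance of directions followed the scaling. Rises made up 40.4% of calls with the deposited scaling and 58.4% (1744 up, 1241 down) after centring each array on its median, and quantile normalization gave 1488 up and 1527 down. The count of 3455 fell to 1581 and 1785 without stimulated knockout array 1 or 2.

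The difference between the serum responses of the genotypes, tested as an interaction, addressed the stated purpose. Because each genotype is a single kind of culture, this and the later comparisons cannot separate MED23 loss from other differences between the lines. Jun responded more in knockout cells by 5.54 ± 0.198 on the log2 scale (adjusted p = 1.06e-06), and a second Jun probe set gave 2.50 ± 0.233 (adjusted p = 0.000911). Its mean signal was 2685 in starved wild-type and 96.55 in starved knockout cells, and 15980 and 30780 after serum. Gadd45a and Gadd45g, which encode growth-arrest and DNA-damage proteins, responded more by 3.86 ± 0.437 (adjusted p = 0.00237) and 3.20 ± 0.304 (adjusted p = 0.000911). Gadd45a averaged 28.71 in starved knockout cells and its signal after serum was lower than in wild-type cells, at 298.7 against 1570. Ccl2 responded more by 3.42 ± 0.425 and Ptgs2 by 2.76 ± 0.261. Id2 responded less in knockout cells by -4.65 ± 0.587 (adjusted p = 0.00382), with a second probe set at -4.44, and Id1 by -3.38 ± 0.386 (adjusted p = 0.00245). Id1 averaged 1194 and 15990 before and after serum in wild-type cells, and 4919 and 6642 in knockout cells.

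Immediate early transcription factors responded more in knockout cells in 12 of 27 cases and less in 1, with 14 not past the test (15 and 2 adjusted over the list alone), and their median difference was 0.92. The list passed with camera adjusted p = 7.57e-07, and had adjusted p = 0.248 with an estimated correlation. Egr1, Jund at 1.86 ± 0.194 and Myc at 1.15 ± 0.161 were among the 12, and Bhlhe40, a clock-linked repressor, was the 1 that responded less, at -1.77 ± 0.183. Fos, Fosb and Nr4a1 had differences of -0.14, -0.30 and 0.12, with adjusted p of 0.804, 0.499 and 0.842. The count of 12 fell to 6 without starved wild-type array 2 or stimulated wild-type array 2, and to 5 without stimulated knockout array 1 or 2. In starved cells 13 of the 27 were lower and 6 higher in the knockout, and after serum 5 were lower and 10 higher, with median differences of -0.25 (-0.43 without starved knockout array 2) and 0.39 (0.21 without stimulated wild-type array 2 and 0.23 after quantile normalization). Of the 12 with a larger response, 9 were lower in starved knockout cells, a level that is subtracted in the response itself. Feedback genes responded more in 7 cases and less in 1 of 27 (11 and 2 adjusted over the list alone), with Dusp1, a phosphatase that switches off MAP kinases, at 2.07 ± 0.247, a median of 0.66 and camera adjusted p = 6.37e-06 (adjusted p = 0.134 with an estimated correlation), and 2 responded less without starved knockout array 1.

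TGF-beta and BMP targets went the other way, with 6 responding less in knockout cells, 1 more and 8 not past the test of 15 (7 and 1 adjusted over the list alone). Id4 stood at -2.57 ± 0.273 (a second probe set at -0.35 did not pass, adjusted p = 0.722) and Id3 at -1.76 ± 0.223, and the list median was -0.71 with camera adjusted p = 0.000419 (adjusted p = 0.248 with an estimated correlation). It was -0.44 without stimulated wild-type array 1 and -0.48 after quantile normalization, and the 1 larger response was lost (0 larger) without any array other than the starved wild-type ones. In starved cells Id2 and Id4 were higher in the knockout, by 4.33 ± 0.233 and 3.63 ± 0.193. Cholesterol genes gave 3 larger responses among 15 (6 larger and 1 smaller adjusted over the list alone), with Sc5d at 1.43 ± 0.169 and Stard4 at 1.36 ± 0.194, a median of 0.45 and camera adjusted p = 0.00188. That call had adjusted p = 0.576 with an estimated correlation and 0.0588, with a median of 0.22, without starved wild-type array 2. Early secreted proteins gave 5 larger and 2 smaller responses among 18 (8 and 4 adjusted over the list alone), with a median of 0.20 and camera adjusted p = 0.0278. The median was 0.04 and 0.11 without starved or stimulated wild-type array 2, and 0.39, 0.47, 0.36 and 0.35 without starved wild-type array 1, starved knockout array 2, stimulated wild-type array 1 or stimulated knockout array 1. That call had adjusted p = 0.29 with an estimated correlation and 0.132 after quantile normalization, and 0.0767, 0.0976 and 0.0552 without starved wild-type array 2, starved knockout array 1 or stimulated wild-type array 2; the larger responses fell to 3 without stimulated wild-type array 1 and to 2 without either stimulated knockout array, and the smaller ones to 0 without starved wild-type array 1, stimulated wild-type array 2 or either stimulated knockout array and to 1 without any other array. Heat-shock and unfolded-protein genes gave 2 larger among 17 (5 larger and 1 smaller adjusted over the list alone), with a median of 0.50, or 0.29 without starved wild-type array 2, and camera adjusted p = 0.00119 (adjusted p = 0.402 with an estimated correlation). Targets of p53 gave 2 larger among 20 (4 and 0 adjusted over the list alone), with a median of 0.36, or 0.24 without stimulated wild-type array 2, and camera adjusted p = 0.00455 (adjusted p = 0.29 with an estimated correlation). Both counts of 2 fell to 0 without either stimulated knockout array, and that of the heat-shock list without stimulated wild-type array 2. The heat-shock count was 1 without either starved wild-type array, and the p53 count was 1 without starved knockout array 2 or either stimulated wild-type array.

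Other genes with a smaller response in knockout cells were Atoh8 at -4.12 ± 0.58, Fbxo32 at -3.96 ± 0.276, Fam43a at -3.81 ± 0.38, Zfp319 at -3.53 ± 0.539 (-1.24 on a brighter probe set) and Sox9, the cartilage transcription factor, at -2.77 ± 0.373. Those with a larger response included Smarcb1, a chromatin remodelling subunit, at 2.74 ± 0.292 (-0.20 on a brighter probe set, adjusted p = 0.599), Sgk1 at 2.22 ± 0.14 and the calponin Cnn1 at 1.67 ± 0.225. In all, 402 probe sets had a response that differed between genotypes, 241 higher and 161 lower in knockout cells. Of the 241, 60 rose in both genotypes and 166 were called up in knockout cells without a call in wild-type cells. Of the 161, 103 were called down in knockout cells without a call in wild-type cells, and 30 were called up in wild-type cells without a call in knockout cells. By the rule of over 2-fold with no overlap, 737 differed, 338 higher and 399 lower; the responses did not overlap for 34.9% of probe sets, against 16.8% of simulated normal values without a difference. No count between the second and first arrays was made for this comparison. After quantile normalization 59.0% of the probe sets passing that rule were higher in knockout cells, against 45.9% with the deposited scaling. The count of 402 fell to 208 and 190 without starved wild-type array 1 or 2, to 210 and 159 without stimulated wild-type array 1 or 2, and to 127 and 176 without stimulated knockout array 1 or 2.

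The responses also had a shared part. Of the 365 probe sets that rose in wild-type cells, 275 rose in knockout cells, where 34.07 would be expected if the calls were independent, and of the 254 that fell, 165 fell (expected 35.01). Of the 619 called in wild-type cells, 92.1% had the same sign in knockout cells (95% exact binomial interval 89.7 to 94.1), and the median ratio of the knockout to the wild-type log2 fold was 0.953. When the 3455 called in knockout cells were taken instead, 80.1% had the same sign in wild-type cells (78.8 to 81.4), and the median ratio of the wild-type to the knockout fold was 0.298. Probe sets are not independent, and choosing them in a genotype inflates that genotype's own fold.

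**Figure D2:**
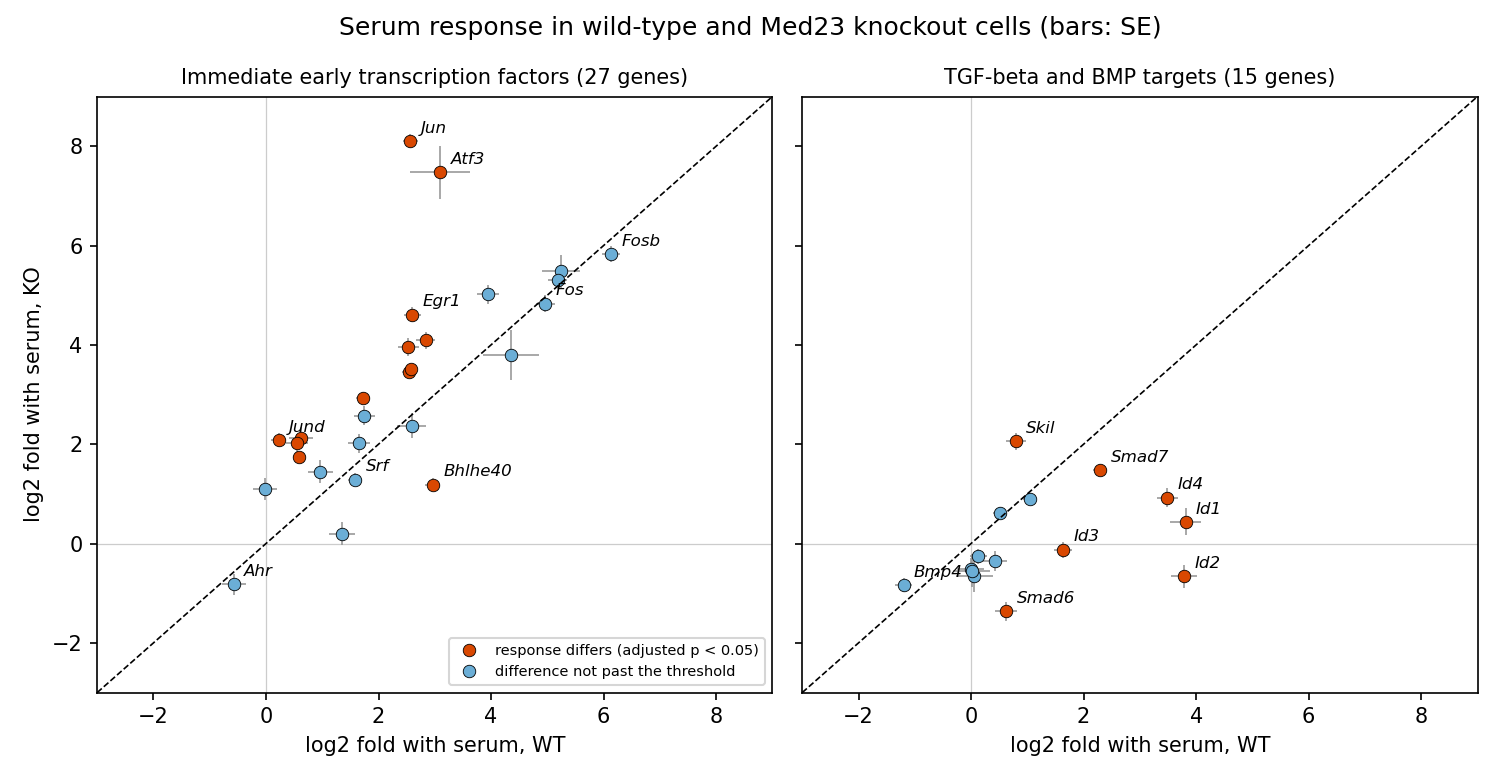
Log2 fold with serum in knockout cells against wild-type cells for 27 immediate early transcription factors (left) and 15 TGF-beta and BMP targets (right); bars are SE, the dashed line marks equal responses, and orange points differ at adjusted p under 0.05. Jun and Egr1 lie above the line, at differences of 5.54 and 2.01, and Id2 and Id1 below it, at -4.44 and -3.38.

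Starved knockout cells against starved wild-type cells gave the baseline on which serum acted. Ptn, a heparin-binding growth factor, was higher in knockout cells 517-fold (log2 9.01 ± 0.294, adjusted p = 2.47e-08), with mean signals of 39.68 and 27250. Slit3, a guidance ligand, was higher 274-fold (log2 8.10 ± 0.183), Cited1 227-fold (log2 7.83 ± 0.199), Sfrp1, a secreted Wnt antagonist, 214-fold (log2 7.74 ± 0.216), and Pdgfra, a receptor for platelet-derived growth factor, 93.1-fold (log2 6.54 ± 0.217). Satb1, a chromatin organiser, was lower 349-fold (log2 -8.45 ± 0.301, adjusted p = 4.04e-08), Asb4 257-fold (log2 -8.01 ± 0.441) and the xenobiotic enzyme Cyp1b1 181-fold (log2 -7.50 ± 0.303). The cell cycle inhibitors Cdkn2b and Cdkn2a were lower 206-fold (log2 -7.68 ± 0.223) and 71.2-fold (log2 -6.16 ± 0.358). Since the lower signals in these ratios lie close to the floor of the arrays, the folds depend on the added constant. Other probe sets of Ptn, Sfrp1, Pdgfra and Satb1 gave smaller differences in the same direction, at 7.30, 2.90 to 5.72, 4.54 and -5.49 on the log2 scale.

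DNA replication and mitosis genes were lower in starved knockout cells in 24 of 27 cases, with none higher (25 and 0 adjusted over the list alone). Their median was -1.54 with camera adjusted p = 5.22e-08, and adjusted p = 0.327 with an estimated correlation. The proliferation antigen Mki67 was lower 6.75-fold, the cyclin Ccna2 5.28-fold, the replicative helicase subunit Mcm2 4.43-fold and Cdc20 3.39-fold. Targets of p53, a list that also holds Cdkn2a, were lower in 12 of 20 cases and higher in 1 (13 and 1 adjusted over the list alone), with Zmat3 lower 2.79-fold and Trp53inp1 2.61-fold, a median of -0.93, or -0.58 without starved knockout array 2, and camera adjusted p = 0.00078 (adjusted p = 0.327 with an estimated correlation). Stress genes were lower in 12 of 17 and higher in 2 (12 and 2 adjusted over the list alone), with Trib3 lower 14.5-fold and Asns, asparagine synthetase, 3.4-fold, a median of -0.66 and camera adjusted p = 0.0108 (adjusted p = 0.42 with an estimated correlation). Early secreted genes were lower in 9 of 18 and higher in none (9 and 0 adjusted over the list alone), with Lif lower 12.5-fold, a median of -0.41 and camera adjusted p = 0.014 (adjusted p = 0.327 with an estimated correlation). NF-kB feedback genes were lower in 8 of 15 and higher in 2 (9 and 2 adjusted over the list alone), with the chemokine Ccl5 lower 28.9-fold, a median of -0.42 and camera adjusted p = 0.0196 (adjusted p = 0.327 with an estimated correlation); 1 was higher without either starved wild-type array, starved knockout array 2 or either stimulated knockout array.

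Cholesterol genes were higher in starved knockout cells in 9 of 15 cases and lower in none (9 and 0 adjusted over the list alone), with Idi1 higher 2.14-fold, a median of 0.67 and camera adjusted p = 0.0086. That call had adjusted p = 0.544 with an estimated correlation and 0.0635, with a median of 0.35, without starved wild-type array 1. Fibroblast matrix genes were higher in 16 of 27 and lower in 6 (16 and 6 adjusted over the list alone), with Col6a3 higher 9.95-fold, Fbln1 7.07-fold and Postn 4.73-fold. Their median was 0.46 with camera adjusted p = 0.014 (adjusted p = 0.544 with an estimated correlation), and after quantile normalization the median was 0.09 with adjusted p = 0.344. Short lists of markers of other cell types did not pass (camera adjusted p between 0.0694 and 0.729). Of these, adipocyte genes were higher in 3 of 4 and lower in none (3 and 0 adjusted over the list alone; median 1.66, camera adjusted p = 0.0694, fry adjusted p = 0.000726), with camera adjusted p = 0.0116 without starved wild-type array 2 and 0.0491 without either stimulated knockout array, and 1 lower without starved wild-type array 1. Neural and glial genes were lower in 4 of 6 and higher in 1 (4 and 1 adjusted over the list alone; median -1.53, camera adjusted p = 0.369, fry adjusted p = 0.0105). Cartilage and bone genes were higher in 3 of 6 and lower in 2 (4 and 2 adjusted over the list alone; median 0.79, camera adjusted p = 0.304, fry adjusted p = 0.000726), with 1 lower without starved wild-type array 2, starved knockout array 1 or stimulated knockout array 2. Ribosomal protein genes were higher in 12 of 14 and lower in none (12 and 1 adjusted over the list alone), with Rps6 higher 4.23-fold, a median of 0.49 and camera adjusted p = 0.00561 (adjusted p = 0.544 with an estimated correlation); after quantile normalization 3 were higher and 1 lower, and their median was 0.08 with adjusted p = 0.457, and 1 was lower without starved knockout array 2. Imprinted genes were higher in 7 of 13 and lower in 2 (8 and 2 adjusted over the list alone), with Sgce higher 33.8-fold and Mest 18.1-fold and Ndn lower 4.88-fold, a median of 0.36, or 0.59 without starved knockout array 1, and camera adjusted p = 0.0457. That call had adjusted p = 0.327 with an estimated correlation, 0.101 after quantile normalization and 0.0601 after median centring; it had 0.05 without starved wild-type array 1, 0.0642 without starved knockout array 2 and 0.0548 without either stimulated wild-type array. The list of Xist and Y-linked genes was higher in 4 of 4 (4 and 0 adjusted over the list alone), with Kdm5d higher 2.37-fold, a median of 1.01 and camera adjusted p = 0.0196 (adjusted p = 0.327 with an estimated correlation), and fewer were higher without starved knockout array 2. Xist rested on a single suffixed probe set, at 299 and 355 in starved wild-type and 586 and 595 in starved knockout cells. After serum it read 494 and 422 in wild-type and 447 and 395 in knockout cells. The other Xist probe sets were too dim to be tested. Mediator subunits were lower in 12 of 28, Med23 included, and higher in 4 (12 and 4 adjusted over the list alone), and this list did not pass (camera adjusted p = 0.111, and 0.0395 without starved knockout array 1); 2 were higher without starved wild-type array 2 or starved knockout array 2. For the Mediator list fry gave adjusted p = 0.00143 in starved cells. After serum 12 Mediator subunits were lower and 4 higher, with a median of -0.47, camera adjusted p = 0.143 and fry adjusted p = 0.00125. In all, 7111 of 14947 probe sets differed in starved cells, 3411 higher and 3700 lower in knockout cells. Of the tested probe sets 2881 passed the rule of over 2-fold, against 34 between the second and first arrays. The groups did not overlap for 73.3% of probe sets, where chance gives 33.3%.

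**Figure D3:**
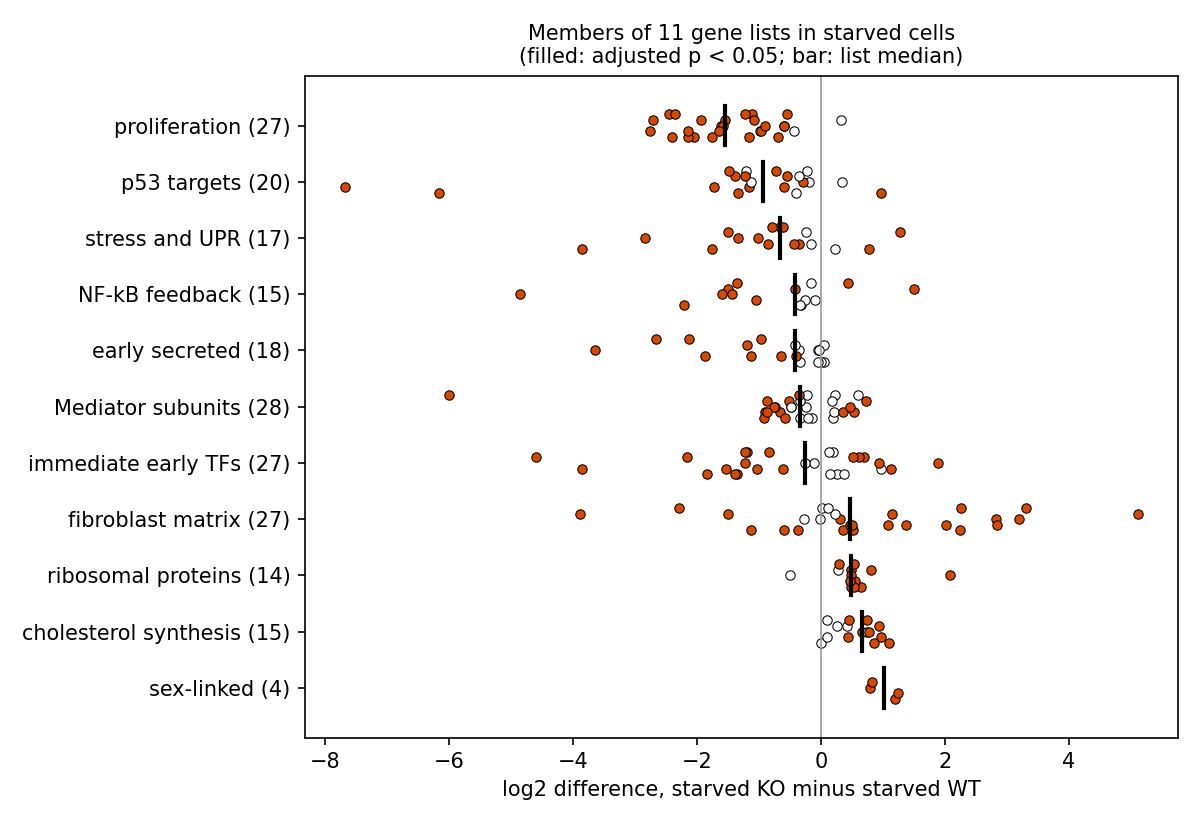
Log2 difference of starved knockout minus starved wild-type cells for the members of 11 gene lists; filled points passed adjusted p under 0.05 and vertical bars are list medians. The proliferation list had a median of -1.54 and the cholesterol list, labelled cholesterol synthesis, of 0.67. After quantile normalization the medians of the fibroblast matrix and ribosomal lists were 0.09 and 0.08.

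Stimulated knockout cells against stimulated wild-type cells compared the levels reached after serum. Ptn was higher 257-fold in knockout cells (adjusted p = 5.71e-08), Pdgfra 222-fold (log2 7.79 ± 0.217), Apod, a lipid-binding lipocalin, 217-fold (log2 7.76 ± 0.199), Abi3bp 213-fold (log2 7.74 ± 0.362) and Svep1 202-fold (log2 7.66 ± 0.223). Satb1 was lower 334-fold (log2 -8.38 ± 0.301), Asb4 290-fold (log2 -8.18 ± 0.441), Pkp1, a desmosome protein, 131-fold (log2 -7.03 ± 0.308) and the adhesion molecule Cadm1 81.5-fold (log2 -6.35 ± 0.384). Other probe sets of Pdgfra, Satb1, Asb4 and Cadm1 gave smaller differences in the same direction, at 4.90, -5.78, -5.88 and -2.79 to -3.72 on the log2 scale. Wild-type means were 59.43 for Ptn, 13.37 for Pdgfra, 76.33 for Apod, 18.49 for Abi3bp and 85.62 for Svep1, and knockout means 8.492 for Satb1, 30.68 for Asb4, 61.73 for Pkp1 and 21.18 for Cadm1. These lie near the floor of the arrays, so the folds depend on the added constant. Among immediate early factors, Klf4 was higher 4.36-fold, Maff 3.5-fold, Jun 1.92-fold, Myc 1.86-fold and Fos 1.75-fold, and Bhlhe40 was lower 3.71-fold. That list was higher in 10 and lower in 5 of 27 (10 and 5 adjusted over the list alone) and did not pass (camera adjusted p = 0.164).

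Cholesterol genes were higher in stimulated knockout cells in 13 of 15 cases and lower in none (13 and 0 adjusted over the list alone), with Idi1 higher 3.93-fold, Sc5d 2.9-fold and Stard4 2.74-fold. Their median was 1.20 with camera adjusted p = 4.19e-05 (adjusted p = 0.545 with an estimated correlation). Replication and mitosis genes were lower in 22 of 27 and higher in none (22 and 0 adjusted over the list alone), with Mki67 lower 4.91-fold, Mcm2 4.33-fold and the mitotic kinase Cdk1 3.56-fold, a median of -1.54 and camera adjusted p = 5.45e-07 (adjusted p = 0.545 with an estimated correlation). Feedback genes were higher in 15 and lower in 3 of 27 (15 and 3 adjusted over the list alone), with Zfp36 higher 1.93-fold, a median of 0.44 and camera adjusted p = 0.0214. That call had adjusted p = 0.545 with an estimated correlation and 0.208 after quantile normalization, and 9 and 6 were higher without stimulated knockout array 1 or 2. SRF targets were higher in 14 and lower in 2 of 26 (14 and 2 adjusted over the list alone), with Myl9 higher 2.84-fold, a median of 0.33 and camera adjusted p = 0.0214 (adjusted p = 0.604 with an estimated correlation, and 0.397 with a median of 0.11 after quantile normalization). Ribosomal protein genes were higher in 11 and lower in 1 of 14 (11 and 1 adjusted over the list alone), with a median of 0.42 and camera adjusted p = 0.0159 (adjusted p = 0.661 with an estimated correlation, and 0.388 with a median of 0.12 after quantile normalization); 6 were higher after quantile normalization, 7 without stimulated wild-type array 1, and 6 without stimulated wild-type array 2 or either stimulated knockout array. In all, 7506 of 14947 probe sets differed, 3400 higher and 4106 lower, and 3069 passed the rule of over 2-fold, against 28 between the second and first arrays. The groups did not overlap for 78.3% of probe sets. Of the probe sets higher in starved knockout cells, 2419 were also higher after serum (expected 775.9), and 2732 were lower in both states (expected 1016).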

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

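A test of bright immediate early members that read higher still after serum in knockout cells, the ratio of counts by the rule of over 2-fold and the test of a variant under the Cdkn2a and Cdkn2b probe sets were chosen only after the results were seen; the other tests were set before their values but after the patterns were seen, the largest pseudocount among them. Of the patterns, the first compares counts of calls, the second is a difference of serum responses and the third a difference at baseline. The responses to serum of 402 probe sets differed between the genotypes by the interaction test.

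The first pattern is the number of probe sets that changed with serum, 3455 in knockout and 619 in wild-type cells, a ratio of 5.58; by the rule of over 2-fold the counts were 1040 and 453, a ratio of 2.30, or 1.53 without the filter and 1.81 to 2.77 with single arrays left out. The Benjamini-Hochberg adjustment was made within each comparison, which set a looser cutoff on p in knockout than in wild-type cells. At an unadjusted limma p under 0.05 the counts were 5485 and 2726, in proportion closer, so the ratio of calls also reflects the adjustment. Scaling of the arrays is argued against for the ratio of calls, which stayed at 4.72 after quantile normalization and 4.85 after median centring. By the rule of over 2-fold the ratios under these were 2.09 and 2.29. A single divergent array is argued against by a ratio of calls between 3.27 and 10 when each array was left out in turn, the lowest without stimulated knockout array 1. Noise of dim probe sets is argued against by ratios of calls of 5.16 with the largest pseudocount and 5.46 with the stricter filter. The rule of over 2-fold gave 2.48 and 2.46 there. The bounds for these explanations were set on the ratio of calls. No ratio by the rule of over 2-fold reached the bound that argues against them, so that rule leaves them undecided. A broader response in the knockout line may be biological, as a hypothesis whose size depends on the rule, but each genotype is a single kind of culture here, so MED23 loss and other differences between the lines cannot be separated by this design.

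The second pattern is the larger fold response of immediate early transcription factors in knockout cells, with a median interaction of 0.917 that included Egr1 at 2.01. The call for this list was lost with an estimated correlation (camera adjusted p = 0.248). Scaling and a single array are argued against by medians of 0.786 to 0.977 and 0.853 to 0.959. Saturation of bright probe sets met the bound set for it beforehand, since the 8 members under the 90th percentile in stimulated wild-type cells had a median of 0.131 (lower quartile -0.32) against 1.08 for the 19 brighter ones. That split used the signal after serum, which the response itself raises, so weakly induced members may be dim. Saturation is thus not shown by this contrast. It is argued against for 5 of the 12 members with a larger response, Jun, Jund, Klf6, Myc and Maff, whose bright probe sets read higher still in stimulated knockout cells; Jund lost that call after quantile normalization (adjusted p = 0.0505) and without stimulated wild-type array 1 (0.124) or stimulated knockout array 1 (0.167), and Klf6 without stimulated wild-type array 2 (0.139) or stimulated knockout array 1 (0.0849) or 2 (0.0816), which leaves 3. Klf4 was not bright in stimulated wild-type cells (2004, against 8643 in knockout cells). For the other 6, Egr1, Junb, Atf3, Ier2, Ier5 and Klf10, saturation may contribute and stays open. These 6 were set apart because none was called higher after serum, and all 6 were lower in starved knockout cells. The response is the level after serum minus the starved level. Their lower starved level thus follows largely from how they were chosen and does not explain the larger response. Egr1 differed by -2.15 in starved cells and by -0.147 after serum. Of the 12, 9 were lower in starved knockout cells, a level that enters the response itself.

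The third pattern is the near absence of Cdkn2a and Cdkn2b in knockout cells. Each gene had a single tested probe set, and these values gave rise to the pattern, so a variant under either cannot be judged. A variant under only a single probe set would not account for both genes. Both of the 2 probe sets were lower, by -6.15 and -7.68 on the log2 scale in starved and by -5.49 and -6.30 in stimulated cells. These sizes depend on the added constant because the knockout signals lay near the floor. Loss of a segment of chromosome 4 could account for it and is not decided. Of the nearest tested genes on the sides of the pair, Mtap was lower by -0.812 and Elavl2 differed by 0.127, with the latter at a low signal. Mtap still averaged 9501 in starved and 8889 in stimulated knockout cells, which argues against a loss of all copies that reaches it. A loss of the pair alone, or of a single copy of a longer segment, stays open. Farther out, in genes named after their values were seen, Caap1, Plaa and Ift74 beyond Elavl2 were lower by -1.32, -0.758 and -0.358. Their limma adjusted p were 0.000425, 0.00147 and 0.0268. Jun, farther out on that side, was lower by -4.592 in starved knockout cells but averaged 30780 after serum, so it was not lost. Beyond Mtap, Ifnz, Klhl9 and Mllt3 differed by 0.648, 0.173 and -0.184 (adjusted p = 0.161, 0.273 and 0.351). Hacd4 on that side was higher by 0.949 (adjusted p = 0.000238). Silencing or deletion of the pair during passage through crisis was not tested.

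Other responses that were larger in knockout cells were Jun at 5.54, Gadd45a at 3.86, Ccl2 at 3.42, Gadd45g at 3.20, Ptgs2 at 2.76 and Smarcb1 at 2.74, the last not on a brighter probe set (-0.20). Atf3 at 4.38, Ccl7 at 3.46, Myo1e at 3.12 and Ccdc25 at 3.07 passed too but lost the call when single arrays were left out. Atf3 then had adjusted p = 0.0579 without starved wild-type array 2, 0.0656 without stimulated wild-type array 2 and 0.0762 and 0.0558 without stimulated knockout array 1 or 2; Ccl7 had 0.077 and 0.0542 without those knockout arrays; Ccdc25 had 0.0586 without starved wild-type array 2 and 0.101 and 0.0509 without those knockout arrays; Myo1e had 0.0635 to 0.135 without each array except starved knockout array 1. Smaller responses were those of Id2 at -4.65, Atoh8 at -4.12, Fbxo32 at -3.96, Fam43a at -3.81, Zfp319 at -3.53 and Id1 at -3.38. Gm13889 at -3.90, Plekhh2 at -3.67, Ppp1r3c at -3.38, on a second probe set than that of its serum values in the report, and Fzd7 at -3.26 passed too but lost the call when single arrays were left out. Gm13889 had adjusted p = 0.0554 to 0.171 without each array except starved knockout array 1 and stimulated knockout array 2; Plekhh2 had 0.0732 to 0.088 without either starved wild-type array, starved knockout array 2 or stimulated wild-type array 1; Ppp1r3c had 0.0683 to 0.0836 without starved wild-type array 2, starved knockout array 2, stimulated wild-type array 1 or either stimulated knockout array; Fzd7 had 0.0558 to 0.0769 without starved wild-type array 2, starved knockout array 2, stimulated wild-type array 2 or either stimulated knockout array. Of the named genes, Jun, Atf3, Gadd45a, Myo1e, Ccdc25, Fzd7, Ppp1r3c, Zfp319, Plekhh2, Gm13889, Fbxo32 and Id2 had a group mean near the floor of the arrays, so their values depend on the added constant. None of the lists that follow passed camera with an estimated correlation (adjusted p = 0.134, 0.29, 0.248, 0.29, 0.576 and 0.402 in their order). Among lists, the median differences were 0.664 for feedback genes, 0.202 for early secreted proteins, -0.708 for TGF-beta and BMP targets, 0.36 for p53 targets, 0.447 for cholesterol genes and 0.505 for stress genes. With single arrays left out they were 0.0376 to 0.466 for early secreted proteins and as low as 0.239 for p53 targets, 0.225 for cholesterol genes and 0.288 for stress genes, and -0.436 for TGF-beta and BMP targets.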

How the results depend on the processing

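The largest pseudocount, and leaving out single arrays and median centring for the gene lists, were chosen after seeing the data; the other alternatives were set beforehand. Every called result of a named gene kept its direction under every alternative that fitted its probe set. The counts below start from results called in the main fit, and each result counts again for every array left out. Of named gene results, 3534 kept their side of the threshold and 306 lost it when single arrays were left out; without the mean-variance trend 40 lost it, without the filter 29, after quantile normalization 19, with the arrays compared alone 11 and after median centring 10. Of the results of lists other than immediate early transcription factors, whose interaction call was lost with an estimated correlation (adjusted p = 0.248), 29 lost the call with an estimated correlation and 7 after quantile normalization, and with single arrays left out 11 lost and 16 gained it. Among these lists, the calls kept with an estimated correlation were all serum responses. They were feedback and early secreted genes in both genotypes, and TGF-beta and BMP targets in wild-type cells. No list call for the interaction or for knockout against wild type was kept. With fry, which tests whether a list's genes move on balance and not against other genes, 5 lost and 31 gained the call. Those lost were stress genes in wild-type cells (adjusted p = 0.12) and, for the interaction, early secreted (0.0875), p53 (0.0771), cholesterol (0.17) and stress genes (0.0875).

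The counts called with 1 probe set per gene were 2081 for serum in knockout cells, 250 for the interaction, 4253 for starved and 4427 for stimulated cells, and without suffixed probe sets 4534 and 4847 for the last pair, since fewer probe sets were then tested. The interaction count was 250 without the filter and 214 without the trend; the cause was not tested. The rule of over 2-fold gave 249, 617 and 373 probe sets for serum in wild-type cells, in knockout cells and their difference with the largest pseudocount, which shrinks folds of dim probe sets, 262, 644 and 405 with the 60th percentile filter, which tests fewer, and 1274, 1945 and 1739 without a filter, which tests more.

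With single arrays left out, the lone array of a group being assumed to vary like the others, the counts ran from 312 to 705 for serum in wild-type cells, from 1581 to 3215 in knockout cells and from 127 to 495 for the interaction. The share with the same sign ran from 88.4% to 92.6% for probe sets chosen in wild-type cells and from 77.0% to 86.0% for those chosen in knockout cells, and the median ratio from 0.857 to 1.01 and from 0.240 to 0.328; the cause was not tested. With the set number as a replicate block the counts were 634, 3494, 399, 7185 and 7581 for the 5 comparisons in the order of the report, and the Egr1 interaction had adjusted p = 0.00177. The labels give no pairing, and the difference between the second and first arrays correlated across probe sets at r between -0.0343 and 0.214 from group to group. With the block, 1 list lost its call (imprinted genes in starved cells, adjusted p = 0.0524) and 1 gained it (fibroblast matrix genes after serum, adjusted p = 0.0484). Signal over background limits folds against probe sets near the floor, and 2 arrays per group limit the precision of every value.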

Other observations

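The grouping of zinc finger genes was chosen after seeing the data. Zinc finger genes of the Zfp, Zkscan and Zscan families, which encode mostly DNA-binding repressors, gave more falls than rises with serum. Of 136 genes, 20 fell and 2 rose in wild-type cells, with a median log2 change of -0.35, against -0.06 for all genes. In knockout cells 65 fell and 8 rose, with a median of -0.60 against -0.16. The interaction had a median of -0.20 against -0.08 for all genes, with 4 lower and 1 higher in knockout cells. Random gene lists gave interaction medians between -0.221 and -0.044 (95% range), so a larger fall in knockout cells was not shown. The family was grouped because some of its falls had been seen. Without the 10 genes seen then, 14 of 126 fell and 2 rose in wild-type cells (median -0.29), and 55 fell and 8 rose in knockout cells (median -0.54). Whether genes of the family vary together was not tested, so no p-value is given.

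Medians of the difference between starved knockout and wild-type cells varied by chromosome around an all-gene median of 0.002. They were 0.297 on chromosome 16 and 0.273 on chromosome 12, and -0.297 on chromosome 3 and -0.283 on chromosome 5, each with permutation p = 1e-04, the smallest the permutations can give, and a Benjamini-Hochberg value of 2e-04. Chromosome 4, which holds Cdkn2a and Cdkn2b, had a median of -0.214 with the same permutation p. Chromosomes 1, 14, 15 and 19 reached that p too, so it does not set chromosome 4 apart. Genes on a chromosome are not independent, and copy number was not measured.

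Transcripts of the Y-linked genes Eif2s3y and Kdm5d were read in both lines, at mean signals of 1582 and 1332 in starved wild-type cells and 3618 and 3183 in starved knockout cells. For 13 list genes a called second probe set had the opposite sign to the one used, in 18 cases over the 5 comparisons. In 3 of these both were called, all in stimulated cells: Rpl22 at -1.30 and 0.81, Rps9 at 0.69 and -0.49, and Grb10 at 0.26 and -0.36. Fn1, which encodes fibronectin, changed by -0.24 with serum in knockout cells on its brightest probe set (adjusted p = 0.193) and by 2.51 on another (adjusted p = 3.46e-07). Lif differed in its serum response by 0.31 on its brightest probe set (adjusted p = 0.771) and by -1.92 on another (adjusted p = 0.0375).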
